A study of Homo sapiens with 2 samples.

How the data were processed

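RNA sequencing of the MDA-MB-231 cell line, an established human triple-negative breast cancer line, was analysed in 2 libraries, 1 per group. Per the labels, the Control culture was incubated for 24 h and the other culture was incubated for 24 h with 1 µM of a treatment that the labels call CEL. Total RNA was extracted with TRIzol, libraries were made with the NEBNext Ultra RNA kit for Illumina and sequencing was done on an Illumina NovaSeq instrument, per the labels' protocols and the series' design text. Per the submitters' processing notes, HTSeq version 0.5.4 and the GRCh38 genome build were used. The aligner, the annotation release, the filters and the strand setting of the counting are not given in the sources used here, so reads of a gene and of a gene overlapping it on the other strand may not have been told apart.

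The deposited table gives FPKM, the counted reads divided by gene length and by the library total, as computed by the authors, for 60978 genes, with the gene length and the GRCh38 coordinates of each. The FPKM were used as deposited, and the other deposited measurement used was the gene length. For 68.7% of the detected genes the product of FPKM and printed length was a whole multiple of a fixed step in each library, and that step gave a total of 14821148 reads in genes for Control and 17199398 for CEL. Because the lengths are printed without decimals, the whole reads of a further 31.3% were found as the pair of whole numbers that fitted both libraries at 1 shared length, in both steps to a relative tolerance of 1e-06 or tighter. This gave reads for 99.99% of the 24783 genes above 0 in at least 1 library, and the recovered reads summed to 99.9997% of the Control total and 99.9995% of the CEL total. Genes without a name, 354 in the table, held 0.298% of the Control reads and 0.265% of the CEL reads and were not used.

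With 1 library per group, the spread between cultures cannot be estimated, and no difference has a replicate check. No p-value or standard error was therefore made across genes, and differences are described by a fixed rule of size. A gene was counted where it reached 1 FPKM in at least 1 library, and was called higher or lower where log2((CEL FPKM + 1)/(Control FPKM + 1)) was at least 1 from 0. This scale, with its pseudocount of 1 FPKM, understates the change of low genes. Folds given for single genes are plain ratios of FPKM, with an exact conditional binomial 95% interval from the recovered reads. These intervals cover counting error only and compare these libraries, not the conditions. A count of 0 allows up to 3 reads, which is 0.202 FPKM in Control and 0.174 FPKM in CEL for a gene of 1 kb.

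A set of 36 gene lists was fixed before the data were examined. For each list, the members at 1 FPKM or more in at least 1 library were taken as measured. The median log2 fold was given with its order-statistic 95% interval over members and its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins, and members at least 1.5-fold higher or lower on the same scale were counted. Lists with under 5 measured members have no percentile. Some genes belong to more than 1 list, so the lists are not independent of each other. The percentile describes these libraries and is not a test of the treatment. The genes named were also set by a rule fixed beforehand: the 12 highest and the 12 lowest log2 folds among protein-coding genes at 10 FPKM or more in at least 1 library, the 5 highest mean FPKM, up to 4 members with the largest absolute log2 fold in each list, and marker levels. Members that make up a count of 5 or fewer, and other genes said to be so, were named after their values were seen. Some genes that the rule names are not reported here.

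Biotypes were taken from GENCODE 29 through gene identifiers, of which 58437 matched. Of these, 78.0% had the same coordinates there, so the release behind the deposited table is another one. Exon overlap between genes on either strand and the GC content of the longest transcript were computed from the same annotation. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

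The steps were tested on simulated data. Reads were drawn for the 24783 detected genes at their pooled rates, with lengths truncated as in the deposited table. By each of 4 folds (1.5, 2.5, 4 and 8), 25 genes were made higher and 25 lower. They were drawn from genes above a cut slightly under 2 FPKM. Both read counts were recovered for 99.99% of genes, and 95.7% of the counting intervals held the true ratio. The rule of size counted 24 of 25 genes made 4-fold higher and 20 of 25 genes made 2.5-fold higher. It counted 25 of 25 made 4-fold lower, 23 of 25 made 2.5-fold lower and 25 of 25 made 8-fold higher or lower. It counted 0 of 25 made 1.5-fold higher or lower. That fold lies below the rule, though counting error could take a low gene past it. Counting error alone took 69 unchanged genes past the rule upward and 64 downward, and 0 of them reached 10 FPKM. Of 400 random lists of unchanged genes, 5.25% lay outside the central 95% of their matched lists. The simulated genes varied independently, so this checks the calculation and not the percentiles of lists whose members vary together.

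The alternatives planned beforehand were pseudocounts of 0.1 and 5 FPKM, no filter and a filter at 5 FPKM, scaling to a common sum (TPM), to the median, to the upper quartile and by a trimmed mean of log ratios, protein-coding genes only, a 1.5-fold rule, genes whose counting interval excludes 1, and random lists without matching. Removal of the trend of the fold with gene length, in 2 forms, and with GC content, lists matched on length as well, and the exclusion of genes that share 25% or more of their exonic bases were added after seeing the data.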

Results

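The series asks how exosomes of M1 macrophages and CEL act on triple-negative breast cancer. The data used here are the transcriptomes of the cancer cells alone, 1 library of MDA-MB-231 cells left for 24 h without CEL (Control) and 1 library of the same line after 24 h with 1 µM CEL. The libraries held 14821148 and 17199398 reads in genes. In the Control library 22437 genes were above 0 and 13324 reached 1 FPKM, and in the CEL library 22019 and 13063 did. Protein-coding genes took 97.6% of the Control reads and 97.8% of the CEL reads. Mitochondrial genes took 7.14% and 4.06%. Because each group has 1 library, no difference below has a replicate check, and "higher" and "lower" describe the CEL library against the Control library, not the treatment.

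In the CEL library, transcripts of oxidative stress defence controlled by the transcription factor NRF2 were higher, and transcripts of inflammatory cytokines controlled by NF-kappaB were lower. Of 21 measured NRF2 targets, 18 were at least 1.5-fold higher and 0 were lower. Of 24 measured NF-kappaB targets and cytokines, 15 were at least 1.5-fold lower and 0 were higher. At least 1.5-fold lower were also 15 of 25 interferon-stimulated genes, 13 of 27 genes of G2 and M phase and 8 of 13 mitochondrially encoded genes. At least 1.5-fold higher were 19 of 41 ribosomal protein genes and 8 of 20 ATF4 targets, with 0 and 1 lower. Fewer ribosomal protein genes passed this mark once a trend of the ratio with gene length was removed, as given below.

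Across the transcriptome most genes were close in level. Of 13745 genes at 1 FPKM or more in at least 1 library, 371 (2.70%) were at least 2-fold higher in the CEL library, 446 (3.24%) were at least 2-fold lower, and 12928 (94.1%) lay in between. Protein-coding genes, 11488 of the 13745, held 187 of the genes at least 2-fold higher and 235 of those lower. At least 4-fold differences were found for 25 higher and 33 lower genes. The counting interval of the ratio excluded 1 for 265 of the higher and 329 of the lower genes. The median log2 fold was 0.00, with quartiles of −0.29 and 0.28, and Pearson's r across genes, which are not independent replicates, was 0.970. Higher genes made up 45.4% of the genes past 2-fold. This share was 19.0% after the trend with gene length among protein-coding genes at 10 FPKM or more was subtracted from all genes, and 49.2% when the trend was subtracted within 5 bins of expression. It passed to the other side with a pseudocount of 5 FPKM (110 higher and 85 lower, 56.4%), a filter at 5 FPKM (50.7%) and removal of the GC trend (51.0%), and protein-coding genes at 10 FPKM or more had 149 higher and 139 lower. The counts were 590 and 880 with a pseudocount of 0.1 FPKM. On the TPM scale, where the pseudocount and filter of 1 stand for less than 1 FPKM, 714 genes were lower. Neither the counts nor their balance is therefore fixed by these data.

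**Figure D1:**
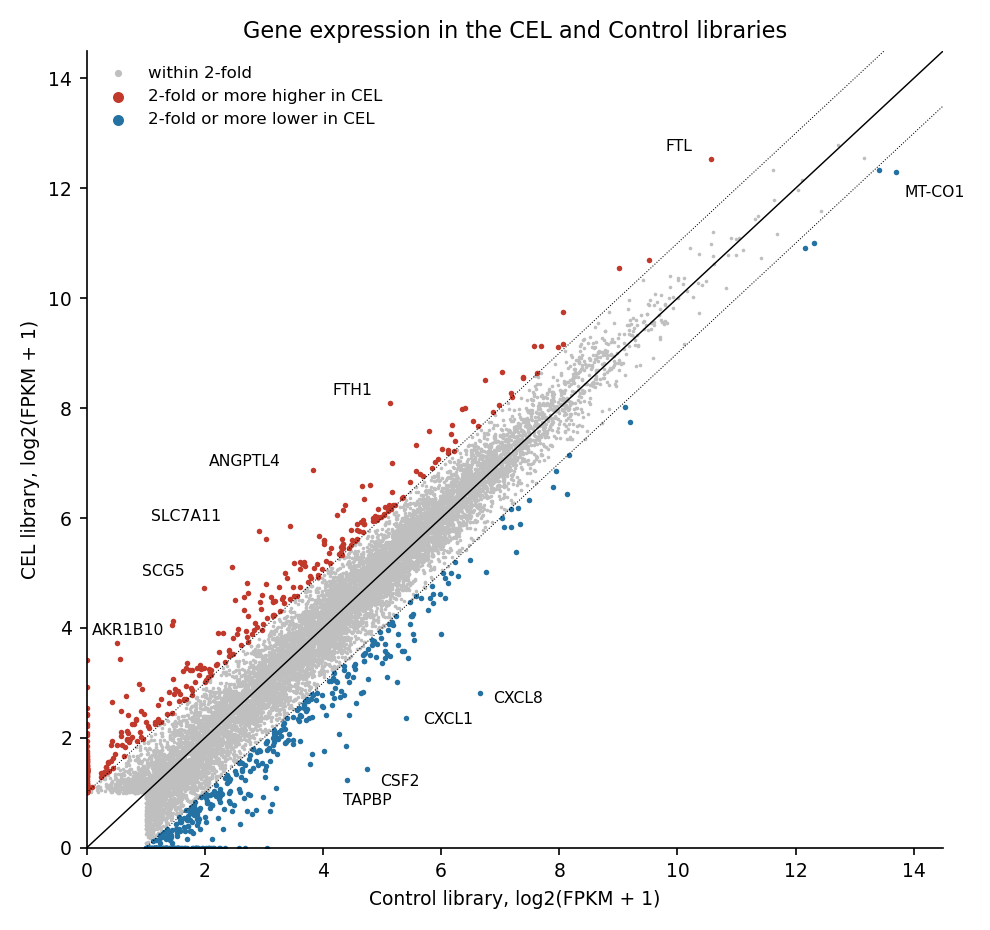
Each point is a gene at 1 FPKM or more in at least 1 library, with log2(FPKM + 1) in the Control library on the x axis and in the CEL library on the y axis; the solid line marks equal levels and the dotted lines mark 2-fold. The 371 red genes were at least 2-fold higher in the CEL library and the 446 blue genes at least 2-fold lower, with CXCL8 and AKR1B10 among the farthest from the line.

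Among protein-coding genes at 10 FPKM or more in at least 1 library, the highest log2 fold belonged to AKR1B10 (ENSG00000198074; GRCh38 chromosome 7, 134527567 to 134541412), an aldo-keto reductase that reduces aldehydes. It stood at 0.428 FPKM (6 reads) in Control and 12.2 FPKM (198 reads) in CEL, a ratio of 28.4 (counting interval 12.8 to 78.4). This rank depends on the pseudocount: at 5 FPKM the log2 fold of AKR1B10 was 1.66, below FTH1 at 2.82 and ANGPTL4 at 2.73. ANGPTL4 (ENSG00000167772; chromosome 19, 8363289 to 8374370), a secreted inhibitor of lipoprotein lipase, was 8.75-fold higher (7.60 to 10.1), at 13.3 and 116 FPKM. SLC7A11, the cystine transporter that feeds glutathione synthesis, was 8.07-fold higher (7.36 to 8.85), at 6.59 and 53.2 FPKM. The iron-storing ferritin subunits were higher as well, FTH1 from 34.3 to 272 FPKM and FTL from 1518 to 5921 FPKM. The collagen-degrading MMP1 was at 9.93 and 56.6 FPKM and the stromelysin MMP3 at 7.19 and 47.9 FPKM. SCG5 (2.97 and 25.4 FPKM), SUN3 (1.72 and 15.7), SEL1L3 (4.70 and 21.8), TRIM16 (24.2 and 94.9) and COA6 (5.67 and 24.0) completed the 12 highest.

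The lowest log2 fold belonged to CXCL8 (ENSG00000169429; chromosome 4, 73740541 to 73743716), the neutrophil chemoattractant interleukin-8. It stood at 100.2 FPKM (1455 reads) in Control and 6.05 FPKM (102 reads) in CEL, 16.6-fold lower (13.5 to 20.4). CSF2 (ENSG00000164400; chromosome 5, 132073789 to 132076170), which encodes the growth factor GM-CSF, was 15.2-fold lower (9.97 to 24.4), at 25.9 and 1.70 FPKM. TAPBP (ENSG00000231925; chromosome 6, 33299694 to 33314387), the tapasin chaperone that loads peptides on MHC class I, was 15.1-fold lower (10.7 to 21.8), at 20.2 and 1.34 FPKM. The chemokine CXCL1 was 10.1-fold lower (7.73 to 13.3), at 41.5 and 4.12 FPKM. PTGES, the terminal synthase of prostaglandin E, was at 19.9 and 2.60 FPKM, and TNFAIP3, an inhibitor of NF-kappaB signalling that NF-kappaB itself induces, was at 20.8 and 4.33 FPKM. CDC42BPG (12.7 and 1.86 FPKM), NEURL1B (15.1 and 2.40), TMEM71 (18.4 and 3.22), PEG10 (62.8 and 13.7) and RCSD1 (13.0 and 2.24) were also among the 12 lowest. The counting intervals of the ratios of these higher and lower genes exclude 1. Of these genes, FTH1 shares 62.0% of its exonic bases with another gene and TRIM16 shares 28.7%, and AKR1B10, FTH1, FTL and TRIM16 have near copies in the genome, so reads may have been split between loci and their levels are uncertain. TAPBP lies in the histocompatibility complex, where reads may be shared with alternate sequences, so its fold is uncertain too.

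The genes with the highest mean level were MT-CO1 (13308 and 5031 FPKM), MT-CO2 (10928 and 5126) and MT-ND4 (9109 and 5961), which encode subunits of respiratory complexes, with ACTB (6756 and 7057) and EEF1A1 (4417 and 4521). The log2 folds of ACTB and EEF1A1, a cytoskeletal actin and a translation elongation factor often used as references, were 0.06 and 0.03. The EEF1A1 value turned negative under 3 other scalings, ACTB turned to −0.11 and −0.14 in the 2 forms of length trend removal, and both turned negative when a trend with GC content was removed.

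The median log2 fold of the NRF2 targets was 1.18 (interval over members 0.87 to 1.76), above all 10000 random lists of matched expression (percentile 100). The 4 largest folds were those of AKR1B10, FTH1, SLC7A11 and FTL. HMOX1, which degrades heme, was at 19.3 and 69.9 FPKM, NQO1, a quinone reductase, at 106 and 364 FPKM, and TXNRD1, which reduces thioredoxin, at 515 and 1497 FPKM; these were chosen after their values were seen. The 3 members that stayed within 1.5-fold were ABCC2, GSR and PGD. Metallothioneins, which bind metal ions, had 4 measured members, too few for a percentile, of which 3 were higher. MT1E was at 54.5 and 190 FPKM and MT2A at 236 and 380 FPKM. MT1A had 1 read in Control and 9 in CEL, a ratio of 7.76 (1.07 to 340).

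**Figure D2:**
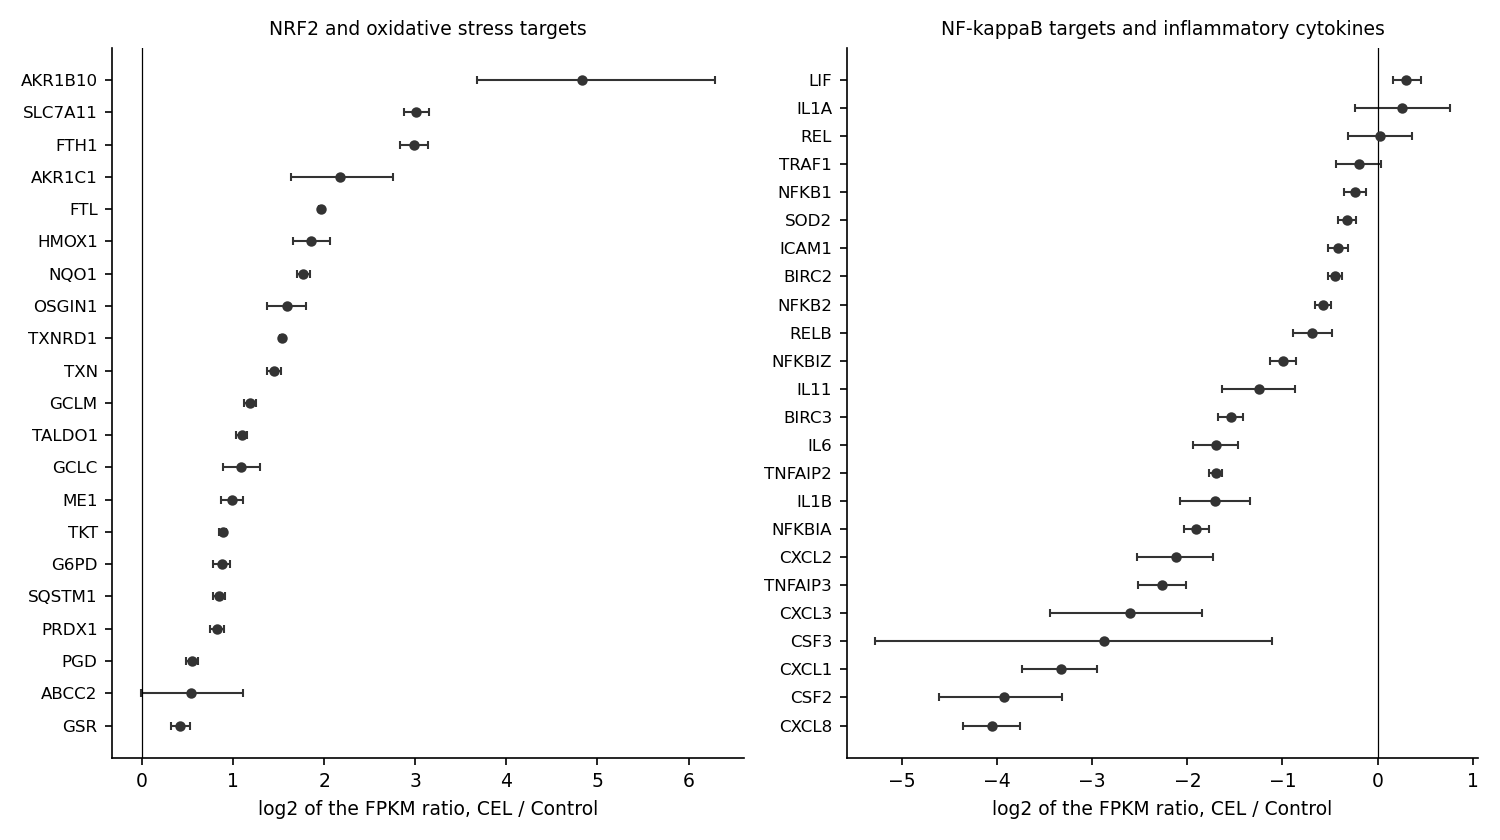
Points give the log2 ratio of FPKM, CEL over Control, on the x axis for each measured member of the NRF2 list (left, 21 genes) and the NF-kappaB list (right, 24 genes); bars are 95% counting intervals, which cover counting error only. Of the NRF2 members 18 were at least 1.5-fold higher, and of the NF-kappaB members 15 were at least 1.5-fold lower.

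Other stress lists differed from each other. ATF4 and integrated stress response targets had a median of 0.40 (0.21 to 0.71; percentile 99.99), with 8 of 20 members higher and 1 lower. SLC3A2, the partner chain of SLC7A11, was at 190 and 557 FPKM, CHAC1, which degrades glutathione, at 0.792 and 4.10 FPKM, and DDIT4, an inhibitor of mTORC1, was the lower member at 69.9 and 42.8 FPKM. Heat shock and cytosolic chaperones had a median of 0.37 (0.12 to 0.60; percentile 99.89), with 6 of 22 higher and 0 lower, HSPE1 at 3.96 and 14.1 FPKM and HSPB1 at 207 and 395 FPKM. HSPA1A had 0 reads in Control and 1 in CEL, and HSPA1B had 0 in both, so this median does not cover them. Both lie in the histocompatibility complex, where reads may have been lost from the counts. Proteasome subunits had a median of 0.39 (0.34 to 0.51; percentile 100), with 5 of 31 higher and 0 lower, PSMA5 at 105 and 179 FPKM, and the median was 0.26 and 0.23 in the 2 forms of length trend removal. The count of higher proteasome members was 3 on the TPM scale and 2 with median or upper quartile scaling and without the length trend. Genes of the endoplasmic reticulum unfolded protein response had a median of −0.16 (−0.28 to 0.13; percentile 0.71), with 1 higher and 2 lower of 20. This percentile was as high as 7.03 under other settings. The p53 targets had a median of −0.25 (−0.41 to 0.13; percentile 1.27), with AEN and BAX higher and FDXR and BBC3 lower among 18, and the median was −0.12 (percentile 10.9) with a filter at 5 FPKM. Apoptosis regulators, with a median of 0.10 and percentile 76.9, had 2 higher and 3 lower among 23, and medians as low as 0.034 under other settings. Autophagy and lysosome genes had a median of 0.20 (0.08 to 0.32; percentile 93.4), with SQSTM1 and CTSL higher among 20, and the median was 0.13 and 0.12 without the length trend.

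The NF-kappaB targets and inflammatory cytokines had a median log2 fold of −1.01 (−1.80 to −0.41; percentile 0), led by CXCL8, CSF2, CXCL1 and TNFAIP3. Interferon-stimulated genes, which act in antiviral defence, had a median of −0.74 (−1.14 to −0.29; percentile 0), with 15 of 25 lower and 2 higher. IFIT3 was at 107 and 31.3 FPKM, IFIT1 was at 39.2 and 11.0 FPKM, OASL and OAS3 followed, and the higher members were BST2 and IFITM1, of which 1 passed 1.5-fold under each of the 4 other scalings and 0 in 1 form of length trend removal. MHC class I antigen presentation had a median of −0.42 (−0.71 to −0.04; percentile 0.06), with 4 of 13 lower and 0 higher. These were TAPBP, HLA-F, ERAP2 and HLA-B, and the reads of HLA genes may be shared among near copies. Immediate early transcription factors had a median of −0.14 (percentile 8.24), which turned to 0.075 (percentile 76.3) with no filter on low values, with 3 higher, MYC among them at 45.1 and 76.7 FPKM, and 1 lower of 15, FOSL2 at 144 and 79.4 FPKM.

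The series' subject includes the function of macrophages, which cancer cells recruit through secreted signals. The list of recruitment and polarisation signals had a median of −0.15 (−1.26 to 0.22; percentile 7.19), with 4 of 13 members lower and 1, THBS1, higher. The median turned to 0.053 (percentile 64.4) with no filter on low values and was −0.36 (percentile 0.37) when centred on the median. Besides CSF2, the lower members were IL6 (44.9 and 13.8 FPKM), CX3CL1 (3.58 and 0.915 FPKM) and the monocyte chemoattractant CCL2. CCL2 had 21 reads in Control and 3 in CEL and was 8.12-fold lower (2.43 to 42.5). CSF2 and IL6 are also members of the NF-kappaB list and are counted as lower in both. Surface signals of phagocytosis and immune checkpoints had a median of −0.18 (−0.39 to 0.17; percentile 1.96, or 6.18 among lists matched on length) and went both ways among 17 members. CD274, which encodes PD-L1, was higher at 10.5 and 21.9 FPKM, as were MICA and PVR. CD24 (2.84 and 0.906 FPKM), LGALS9, TNFRSF14 and CALR (1322 and 850 FPKM) were lower. CD47, which inhibits uptake by macrophages, was within 1.5-fold at 59.2 and 44.9 FPKM, log2 fold −0.39, and was chosen after its values were seen.

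Genes of G2 and M phase had a median of −0.56 (−0.67 to −0.47; percentile 0), with 13 of 27 lower and 0 higher. KIF20A, a kinesin of cytokinesis, was at 236 and 93.3 FPKM, and the mitotic kinase PLK1 at 115 and 60.2 FPKM. DLGAP5 was at 185 and 101 FPKM and CDC25C at 25.7 and 14.2 FPKM. S phase genes had a median of 0.23 (0.17 to 0.42; percentile 97.3), with 27 of 28 members within 1.5-fold. The exception was CDC6, which licenses replication origins, at 72.4 and 121 FPKM. Replication-dependent histones had 6 measured members, a median of 0.13 and percentile 82.8, with 1 lower, and the median turned to −0.18 in 1 form of length trend removal.

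**Figure D3:**
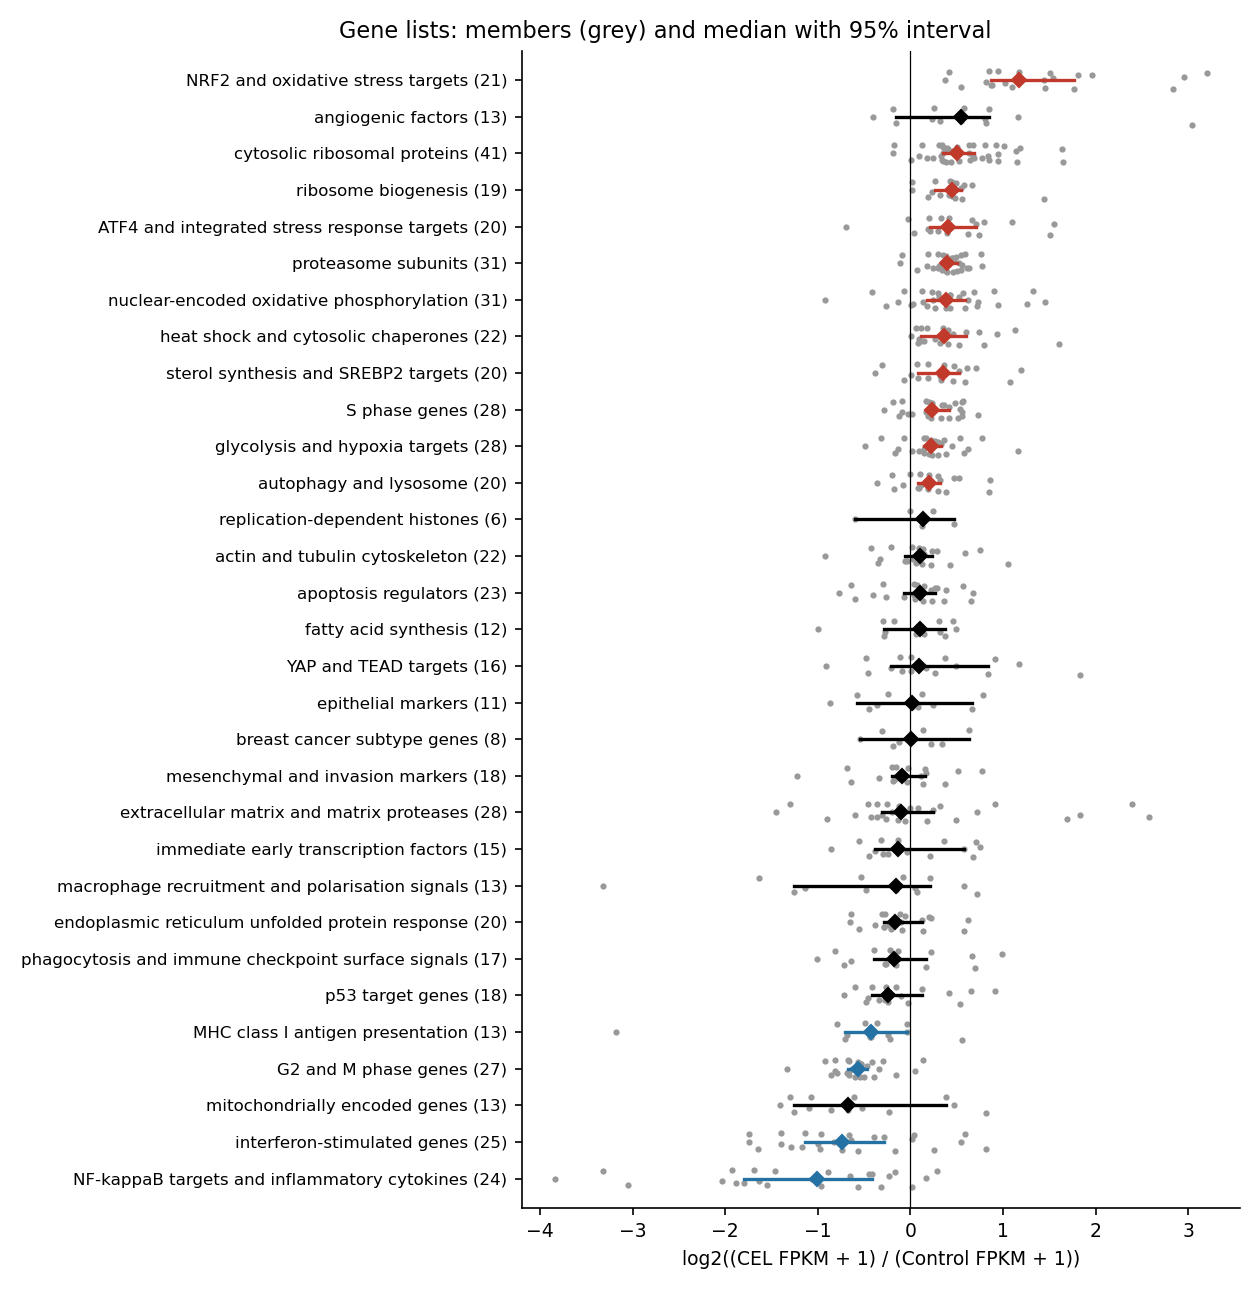
Each line is a gene list with its number of measured members in brackets; grey points are members, diamonds are medians of log2((CEL FPKM + 1)/(Control FPKM + 1)) and bars are 95% intervals over members, red where above 0 and blue where below 0. Of 31 lists, 11 intervals lay above 0 and 4 below, with the NRF2 list at the upper end and the NF-kappaB list at the lower end.

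Cytosolic ribosomal proteins had a median of 0.50 (0.36 to 0.69; percentile 100), with 19 of 41 higher and 0 lower, among them RPL37 (49.2 and 110.5 FPKM) and RPS27 (80.5 and 253 FPKM). The median was 0.27 and 9 or 10 members were higher when the trend with gene length was removed, and processed pseudogenes of these genes may take part of their reads. Ribosome biogenesis genes had a median of 0.45 (0.26 to 0.55; percentile 99.99), with NOP16 and NOLC1 higher among 19. Nuclear-encoded subunits of oxidative phosphorylation had a median of 0.38 (0.18 to 0.59; percentile 100), with 10 of 31 higher and NDUFB8 lower, and COX6C at 11.2 and 32.5 FPKM. Without the length trend this median was 0.09 at percentile 85.6 in 1 form of the removal and 0.11 at percentile 95.6 in the other, with 4 members higher in both. Mitochondrially encoded genes had a median of −0.67 (−1.26 to 0.39; percentile 0), with 8 of 13 lower and 1, MT-ND4L, higher (0 without the length trend), and nuclear copies of mitochondrial DNA may share their reads. MT-ND4L overlaps MT-ND4 and MT-ATP8 overlaps MT-ATP6, so their values are uncertain.

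**Figure D4:**
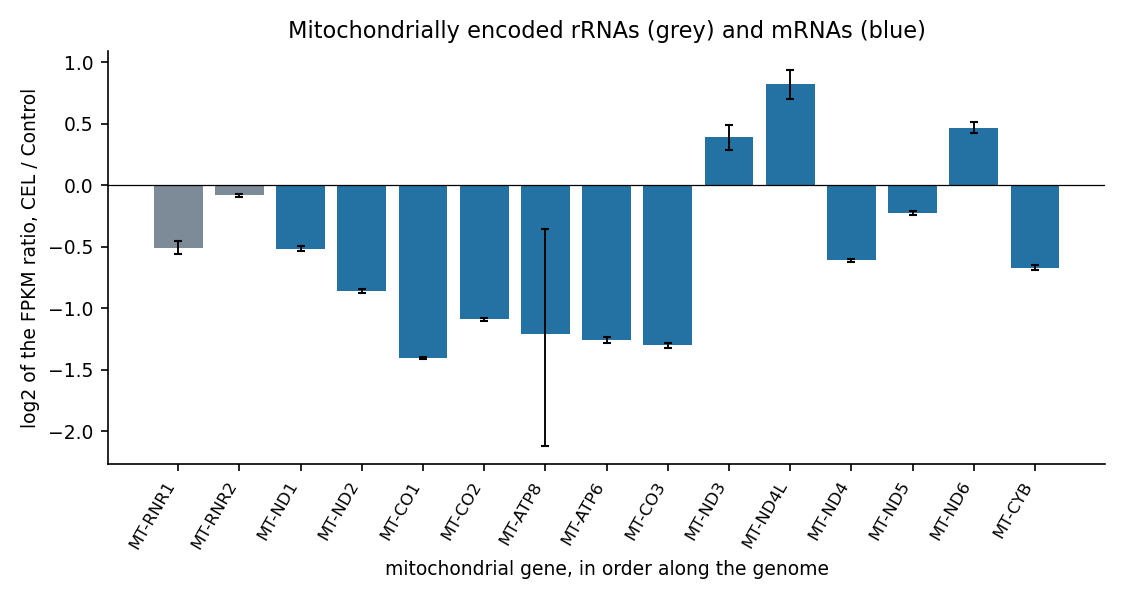
Bars give the log2 ratio of FPKM, CEL over Control, on the y axis for each mitochondrial rRNA (grey) and mRNA (blue) in order along the mitochondrial genome; error bars are 95% counting intervals. MT-CO1 was lowest at −1.40 on the pseudocount scale and MT-ND4L highest at 0.82.

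The ratio of the libraries also varied with gene length over the 8170 protein-coding genes at 10 FPKM or more in at least 1 library. This length is the 1 value per gene that was deposited. How it was derived is not known here, so it may differ from the length of the transcripts sequenced. Spearman's correlation across genes was −0.295. The tenth with the shortest genes had a median log2 fold of 0.33 (0.31 to 0.36) and the tenth with the longest −0.13 (−0.16 to −0.10). The correlation with GC content was −0.11.

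**Figure D5:**
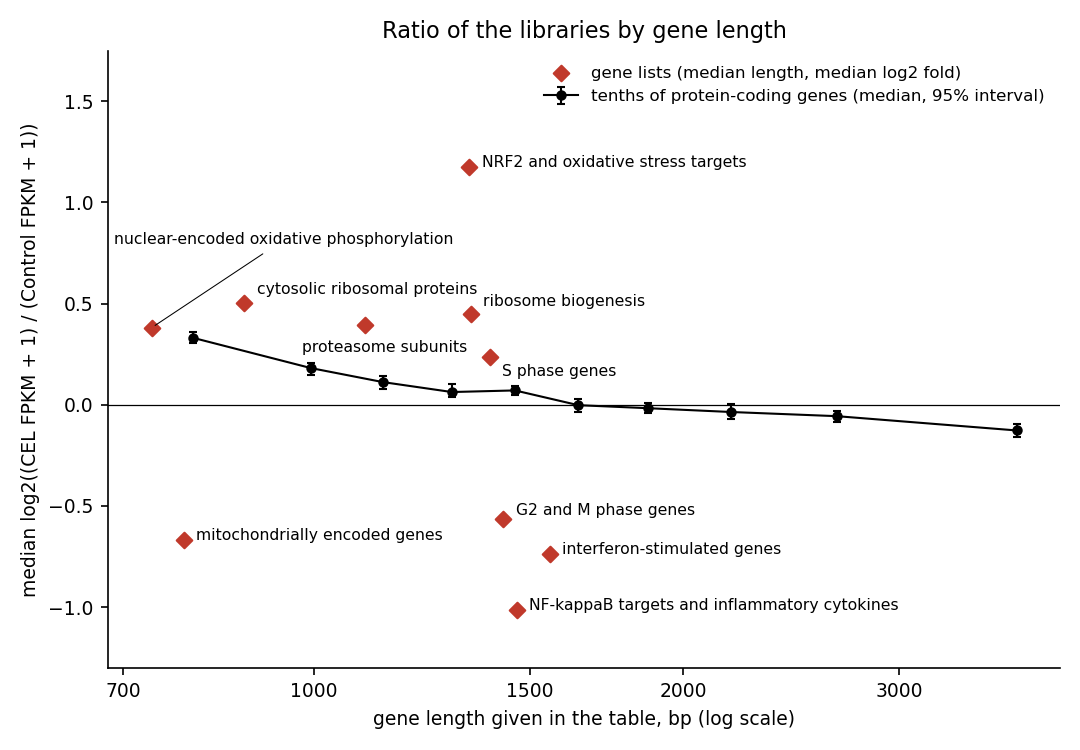
Black points are 10 equal groups of 8170 protein-coding genes by gene length, with the median length on the x axis (bp, log scale) and the median log2 fold with its 95% interval on the y axis; red diamonds are gene lists at their median length and median log2 fold. The black line runs from 0.33 to −0.13, and the diamonds of NRF2 targets at 1.18 and NF-kappaB targets at −1.01 lie away from it.

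Among metabolic lists, sterol synthesis genes had a median of 0.35 (0.08 to 0.53; percentile 99.89), with 5 of 20 higher and 0 lower, and the sterol sensor INSIG1 at 24.8 and 58.0 FPKM, and 3 were higher on the TPM scale and with median or upper quartile scaling. Fatty acid synthesis genes had a median of 0.10 (percentile 60.6), with the lipogenic regulator SREBF1 lower at 97.8 and 48.5 FPKM among 12, and medians as low as 0.049 under other settings. Glycolysis and hypoxia targets had a median of 0.22 (0.15 to 0.33; percentile 95.1), with ADM, HK2 and EGLN3 higher among 28, and the median was 0.13 and 0.14 without the length trend. Angiogenic factors had a median of 0.55 (−0.16 to 0.85; percentile 99.99), with 5 of 13 higher, ANGPTL4 and EREG (32.0 and 72.7 FPKM) among them, and the median was 0.32 with no filter on low values.

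Genes of matrix and invasion went both ways. Extracellular matrix and protease genes had a median of −0.10 (−0.31 to 0.25; percentile 1.17) and a mean of 0.15, with 6 higher and 4 lower among 28. The percentile was 16.3 and 14.6 without the length trend and 5.29 among lists matched on length. MMP1, MMP3 and CCN2 (34.9 and 127 FPKM) were among the higher, and LAMA5, COL1A1, TNC and COL6A1 were lower. Mesenchymal and invasion markers had a median of −0.09 (percentile 9.01), with the laminin receptor subunit ITGB4 (133 and 56.2 FPKM), ITGB1 and CDH11 lower and TGFBI higher among 18, and medians ranged from −0.14 to −0.051 under other settings. Epithelial markers had a median of 0.02 (percentile 50.6), with KRT7 and KRT18 higher and EPCAM lower among 11, and its sign turned under some scalings. The YAP and TEAD targets had a median of 0.09 (percentile 55.1), with 4 higher, among them F3, the initiator of coagulation, at 735 and 1659 FPKM, and 1, NUAK2, lower of 16, and medians ranged from 0.019 to 0.17 under other settings. Actin and tubulin genes had a median of 0.11 (percentile 62.2), with TUBA1B, TAGLN and MYL9 higher and TUBB3 lower among 22, and medians as low as 0.018 under other settings. Breast cancer subtype genes had a median of 0.01 (percentile 42.0) that turned negative under other scalings, with FOXC1 higher among 8. ERBB2 was at 71.7 and 48.8 FPKM and EGFR at 123 and 156 FPKM.

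Most markers of other cell types were under 1 FPKM in both libraries. Of 22 macrophage and myeloid markers 3 reached 1 FPKM, LAPTM5 (11.3 and 7.89 FPKM), CSF1R (2.78 and 1.81) and CD14 (1.92 and 1.36). Of 12 lymphocyte markers CD8A alone did, at 2.92 and 2.33 FPKM. Of 11 fibroblast markers 4 did, of which COL1A1 and ACTA2 were at least 1.5-fold lower, LUM was higher and PDGFRB was at 11.4 and 12.8 FPKM. Of 8 endothelial markers 2 did, EGFL7 at 40.3 and 69.7 FPKM and ESAM at 24.5 and 26.1 FPKM.

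Members counted as at least 1.5-fold higher or lower in these lists had counting intervals that exclude 1. Small counts depend on the setting: with a pseudocount of 5 FPKM the lower members were 2 for MHC class I, 2 for macrophage signals, 1 for checkpoint signals, 0 for p53 targets and 0 for apoptosis regulators, and the higher member of the unfolded protein response was lost under 3 scalings. The intervals and percentiles describe these libraries, and differences between cultures handled alike could not be measured with 1 library per group.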

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

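The removal of length and GC trends, the matching on length and the exclusion of overlapping genes were chosen after seeing the data. No paired analysis was possible because each group had 1 library. Over these alternatives and the planned ones, 454 list medians stayed within their interval over members and 10 left it. Of medians whose interval excludes 0, 0 changed sign. Settings that alter only the random lists cannot move a median and are among these cases. Of the named genes' log2 folds, 304 stayed within their counting interval, 64 left it, and 7 changed sign. Filters, the restriction to protein-coding genes and the exclusion of overlapping genes cannot move a gene's own ratio. Their cases, with a largest move of 0, are among the 304. Counts of genes past 2-fold stayed within 1.5 times in 17 cases and left that range in 13. Removing the filter could not change these counts, because a gene under 1 FPKM cannot pass the rule at a pseudocount of 1 FPKM. They were 590 higher and 880 lower with a pseudocount of 0.1 FPKM, and 110 and 85 with 5 FPKM. A filter at 5 FPKM left 214 and 208, protein-coding genes alone gave 187 and 235, and a 1.5-fold rule gave 1233 and 1398. Fewer genes can only lower such counts, and a wider rule can only raise them. Protein-coding genes were 11488 of the 13745 genes but held only 187 of the 371 higher and 235 of the 446 lower. Genes of other biotypes therefore passed the rule more often. TPM gave 714 lower genes among 14903. The FPKM summed to 666938 in Control and 685382 in CEL, so 1 TPM stands for less than 1 FPKM. The pseudocount and filter of 1 were therefore lower on that scale. Centring on the median had a larger scale factor (1.036 against 1.028) and gave 492 lower genes. With the length trend of protein-coding genes at 10 FPKM or more subtracted from all genes the counts were 167 and 710. Proteasome medians were 0.34 when centred on the median, 0.23 and 0.26 under the 2 length corrections and 0.33 under the GC correction. The length corrections gave 0.14 and 0.13 for glycolysis and hypoxia, 0.11 and 0.086 for oxidative phosphorylation, and 0.28 and 0.27 for ribosomal proteins. EEF1A1 became −0.0064 with TPM, −0.018 when centred on the median, −0.012 with the upper quartile and −0.010 with the GC correction. The first 3 scale CEL down against Control by factors of 1.028, 1.036 and 1.032. Such a factor moves every abundant gene alike and took the small value of EEF1A1 below 0. ACTB became −0.11 and −0.14 under the length corrections and −0.028 under the GC correction. Apart from the cases whose construction is given, the cause was not tested. Depth limits low genes, since 3 reads in a 1 kb gene are 0.202 FPKM in Control and 0.174 FPKM in CEL.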

Other observations

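The matching on length, the removal of the length trend, and the tests of transcripts with a 5' terminal oligopyrimidine tract, of uniform mitochondrial loss, of shared exons and of alternate histocompatibility sequences were chosen only after the result was seen, as were the genes and families in the next paragraph.

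Of 19 counted SNHG genes, which host small nucleolar RNAs, 9 were at least 1.5-fold higher and 1 was lower, with a median log2 fold of 0.58, and this family was picked for its values, so its size is a description and no test. SNHG5 was at 22.9 and 58.6 FPKM and DANCR, another such host, at 19.1 and 43.7 FPKM. NMRAL2P, a pseudogene RNA, was 9.40-fold higher (6.07 to 15.3), and the xenobiotic enzymes PTGR1 (46.9 and 160 FPKM) and MGST1 (129 and 404 FPKM) were higher. Among single genes, BTN3A1, BTN3A2 and BTN3A3, which signal phosphoantigens to gamma-delta T cells, had log2 folds of −1.59, −1.27 and −1.11. Of 5 counted guanylate binding proteins 3 were at least 1.5-fold lower and 2 lay between, with GBP4 at 33.0 and 7.67 FPKM, and the kinase IKBKE was at 37.6 and 11.9 FPKM.

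The ribosomal protein, proteasome and oxidative phosphorylation lists had medians above 0, with 19 of 41, 5 of 31 and 10 of 31 members at least 1.5-fold higher (9 or 10, 2 and 4 without the length trend), and the median fold of protein-coding genes was above 0 at short lengths. Among lists matched on length as well as expression the percentiles were 100 for ribosomal proteins and 99.97 for the proteasome, which argues against the length trend as the whole cause of these. For oxidative phosphorylation the percentile was 98.8, but the length bins are coarse at the short end, where its median length is 738 bp, and the removals of the trend left medians of 0.09 at percentile 85.6 and 0.11 at percentile 95.6, so whether the length trend may account for it stays open. A shared higher level of transcripts with a 5' terminal oligopyrimidine tract stays open. A set of 14 such genes outside the ribosomal protein list, RACK1 among them, had a median of 0.27 (−0.04 to 0.48). Its members ranged from −0.27 for HNRNPA1 to 0.66 for TPT1, with EEF1A1 at 0.03 and RACK1 at 0.28. The length trend was not removed from these values. The interval of this median overlaps that of the ribosomal list. An effect of CEL was not testable against a difference between cultures.

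Of 13 mitochondrially encoded genes 8 were at least 1.5-fold lower and 1 was higher. A uniform loss of mitochondrial RNA would move the 10 heavy-strand mRNAs with over 1000 reads alike. Their log2 folds ranged over 1.79, from −1.40 for MT-CO1 to 0.39 for MT-ND3, more than counting error allows. MT-ND3 is the shortest of the 10 at 346 bp, so the length trend may widen this range. The next highest was MT-ND5 at −0.23, of 1812 bp, whose counting interval still lies apart from that of MT-CO1, of 1542 bp. This spread argues against a uniform loss alone. A uniform loss joined to technical differences between single genes cannot be excluded, since the intervals cover counting error only. For the median of the list the length trend runs the other way, and the length-matched percentile was 0. A difference in the turnover or processing of these transcripts may remain, and neither it nor a difference between library preparations was tested.

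Some abundant genes were counted near 0 in both libraries, as CYP51A1, NOP2 and NUSAP1 were. Of 4 members of constitutive lists under 1 FPKM, 3 (75%) shared 25% or more of their exonic bases with another gene, against 5.08% of 197 others. Reads in shared exons having been left out of the counts could give this. FDFT1 (0.528 and 0.910 FPKM) shared 4.17%, so this account does not cover it. Short length does not account for the 4 members, since 0 of them were shorter than the 10th percentile of the others. In the histocompatibility complex (chromosome 6, 29 to 34 Mb), 29.4% of 17 list members, TAP2 among them, had 3 reads or fewer in each library against 3.49% of 602 elsewhere, which is consistent with reads shared with alternate sequences of the complex, so levels in that region may be understated. TAPBP lies in it but shares no exonic bases and differed between the libraries, so its fold remains open.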
